A study of Mus musculus with 2 samples.

How the data were processed

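H3K4me1 was measured by chromatin immunoprecipitation and sequencing in liver from mouse embryos of strain B6NCrl at embryonic day 11.5, in 2 biological replicates of 1 group. Per the labels, each replicate combined 2 technical replicates, replicate 1 came from 109 embryos, and both pools held male and female embryos. The labels named possible controls, which were not analysed here. Per the text descriptions deposited with the samples, the coordinates were those of assembly mm10, the lists were in narrowPeak format, and each replicate's list was derived from 1 filtered alignment file of that replicate together with 2 further files for replicate 1 and 1 for replicate 2. Per the same descriptions, the pooled list was derived from the alignments of both replicates, and the replicated list from the pooled list and both replicates' lists. The aligner, the peak caller, its version and its threshold, the nature of the further files, and the rule by which the replicated list was made are not given in the sources used here.

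The deposited lists gave each peak a measure of enrichment, per the narrowPeak format named in the deposited descriptions. That format does not state its unit, and the values were taken here as linear fold enrichments. The same deposited lists gave each peak a p-value and a q-value on the −log10 scale, which the authors' peak caller assigned, per that format. All −log10 p values in the deposited files were above 2. The share of peaks with a q-value of at most 0.01 was 74.4% in replicate 1, 53.8% in replicate 2, 60.4% in the pooled list and 72.0% in the replicated list. Fold enrichment and p-values were used to describe, rank or filter peaks within a list. The only use between lists was a rank correlation of fold enrichment over overlapping peaks of the replicates. The files held no read counts, so the depth of the samples was unknown and no precision based on reads could be given. Lists called at unequal depth would differ in length and in weak peaks, which limits any comparison of the replicates.

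Genes and transcripts were taken from the GENCODE release M21 annotation of the same assembly, with chromosome names and lengths that held every peak. Peaks lay on 20 chromosomes, with 0 on Y in every list. A peak counted as shared when an overlap reached 50% of the length of either peak. Chance overlap came from 100 circular shifts of a list along each chromosome, which keep peak widths and clustering. Intervals of shares are exact 95% binomial intervals. Peak centres were assigned in order of priority to promoters (within 1000 bp of a transcript start), exons, introns and intergenic sequence, and compared with 100 circular shifts. The profile around gene starts used bins of 100 bp over 10000 bp on each side of the 5′ ends of 21728 protein-coding genes.

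For gene lists, coverage was the percentage of the 100 kb centred on the 5′ end of a gene that lay in peaks. A total of 11 lists with 232 genes and the family of olfactory receptors by symbol were fixed before the data were examined. All 232 genes were found in the annotation. The rule for naming genes was fixed then too, as were the tests except those of differences between lists. So were the alternatives other than those named as later choices. Each list's mean was compared with 10000 random lists of protein-coding genes matched on the number of protein-coding gene starts in the window, in 5 density groups, by a two-sided permutation test with Benjamini-Hochberg adjustment over the 12 lists. Differences between lists were tested, after subtraction of the mean of each density group, with 100000 permutations of genes between the lists. Domains were replicated peaks merged over gaps of at most 1000 bp. The protein-coding genes with starts nearest to the 200 longest domains were compared with those nearest to any domain by a one-sided Fisher's exact test for each list with the same adjustment. An adjusted p below 0.05 counted as passing. With 2 samples of 1 group no test across animals was run, and the spread between replicates was given by applying the same steps to each replicate's own list.

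The rule for named genes took the 3 genes with the highest coverage and the 1 with the lowest in each list, always Alb, Afp, Hnf4a, Gata1, Klf1, Tal1 and Hbb-y, the genes nearest to the 10 longest domains, and the genes nearest to the 5 peaks with the highest fold enrichment. Where several genes had no coverage, the last in alphabetical order was named.

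Alternatives were another minimum overlap, a q-value of at most 0.01, lists of equal length, merged peaks, a promoter window of 2500 bp, gene windows of 10 or 100 kb on each side, the pooled list, each replicate's own list, random lists without matching, 1 gene per cluster of list genes within 100 kb, the number of peaks in place of covered length, and other gaps and numbers of domains. Alternatives chosen after the data were seen were top peaks in the make-up of the replicated list, peaks found in both replicates, replicate 1 kept to its top peaks for location and gene lists, lists without their most covered gene, and autosomal genes only. The overlap counts were checked against bedtools 2.31.1 on the same lists and were equal. The gene list test was tested on simulated lists of genes drawn from the 21728 genes, with 200 lists of each kind and 500 random lists per test at an unadjusted p of 0.05. It called 4.5% of unchanged lists of 30 genes and 3% of unchanged lists of 18 genes, 88.5% and 72.5% of those with a planted 2-fold difference, and 100% and 91% of those with a 3-fold difference. The simulated genes were drawn singly. These rates therefore do not cover lists with clusters of neighbouring genes, such as the globin genes of the erythroid list. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.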

Results

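Histone H3 carrying a single methyl group on lysine 4 (H3K4me1), a mark found at enhancers and beside promoters, was mapped by chromatin immunoprecipitation and sequencing in the liver of mouse embryos at embryonic day 11.5, a stage at which the liver bud also houses blood formation. The 2 samples were biological replicates of 1 group. Replicate 1 was liver pooled from 109 embryos, and replicate 2 was also a pool, whose number of embryos the labels did not state. Peaks were listed for replicate 1 (133907 peaks over 55.1 Mb), replicate 2 (58636 peaks over 24.8 Mb), the pooled reads of both (108708 peaks over 49.5 Mb) and a replicated list derived by the authors from these lists (82422 peaks over 43.3 Mb, or 1.65% of the genome). The replicated peaks had a median width of 379 bp and a median fold enrichment of 3.61, a value the authors gave each peak. Read depth was unknown because the files held no read counts. With a single group and no other tissue or stage, the design allowed comparison of the replicates with each other and of genes and regions within the liver.

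The first question was how far the replicates shared their peaks. Most peaks of replicate 2 were found in replicate 1, and fewer of the much longer replicate 1 list were found in replicate 2. Of the replicate 2 peaks, 74.3% (95% exact binomial interval 73.9 to 74.7) were overlapped by a replicate 1 peak over at least 50% of the length of either peak, against a mean of 3.16% and a highest value of 3.81% in 100 circular shifts of replicate 2 along the chromosomes. Of the replicate 1 peaks, 29.9% (interval 29.6 to 30.1) were overlapped by a replicate 2 peak, against 1.39% on average and 1.70% at most in the shifts. The intervals covered counting error only, and neighbouring peaks were not independent of each other.

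Shared peaks were the stronger and wider ones within each list. In replicate 1, shared peaks had a median fold enrichment of 4.13 and unshared peaks 3.29, and in replicate 2 the medians were 3.84 and 3.53. Median widths were 509 and 259 bp in replicate 1 and 360 and 253 bp in replicate 2. Wide peaks can overlap more easily, and strength and width were not separated. Over 45448 overlapping pairs the fold enrichments of the replicates had a Spearman correlation of 0.25. Only peaks listed in both replicates entered, and a peak counted once for each peak it overlapped. The value therefore does not measure agreement of signal over the genome. Among the top decile of replicate 1 peaks by p-value 82.5% were shared, and among the bottom decile 11.4%. The corresponding shares in replicate 2 were 96.2% and 61.7%. With replicate 1 kept to its 58636 top peaks by p-value, 48.9% of them were shared, and 56.1% of replicate 2 peaks were, so the percentages moved with the length of the lists. With the full lists, requiring overlap over 50% of both peaks lowered the shares to 17.8% for replicate 1 and 40.7% for replicate 2.

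The replicated list was made up of peaks of the pooled list with unchanged coordinates, and it kept 75.8% of them. Of the 82422 replicated peaks, 40513 (49.2%) were overlapped by peaks of both replicates' own lists, 38.0% by replicate 1 only, 6.05% by replicate 2 only and 6.77% by neither. Pooled peaks found in both replicates were kept in 100% of cases, those found only in replicate 1 in 66.5%, those only in replicate 2 in 65.1% and those in neither in 41.6%. Because the replicated list was itself derived from both replicates' lists, the 100% may follow from the authors' rule. It is no independent measure of agreement. Kept peaks had a median fold enrichment of 3.61 and a median width of 379 bp, and pooled peaks that were not kept 2.95 and 213 bp. The share in both replicates fell to 29.2% when 50% of both peaks had to overlap.

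Replicated peaks lay mostly in introns and at promoters and were sparse between genes. By the position of their centre, 22.8% lay within 1 kb of an annotated transcript start (replicates 22.0% ± 1.04, SD, n = 2), 3.53 times the mean of 6.44% after circular shifts. Introns held 52.4% (replicates 53.3% ± 1.51, SD, n = 2) against 40.8% after shifts, and exons 5.30% (replicates 5.32% ± 0.443) against 3.45%. Intergenic sequence held 19.5% (replicates 19.5% ± 2.10) against 49.3%. For each class, the difference from the shifted positions was larger than the SD between replicates, and the observed share lay outside the range of the 100 shifts.

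Around the starts of 21728 protein-coding genes the mark flanked the start and was lower at the start itself. Replicated peaks covered 5.72% of genes at 50 bp upstream of the start, 11.7% at 750 bp upstream and 19.0% at 1250 bp downstream, against 3.92% on average at 9 to 10 kb from the start. The same order held in each replicate's own list, with 9.11%, 13.7% and 20.1% at the lowest point and the upstream and downstream maxima in replicate 1, and 2.41%, 6.75% and 12% in replicate 2. Away from starts, 48.2% of replicated peaks were centred 1 to 10 kb from the nearest transcript start and 29.1% more than 10 kb away (replicates 29.4% ± 2.73, SD, n = 2), where the shifts placed 61.2%. Widening the promoter class to 2.5 kb from a transcript start raised its share from 22.8% to 40.4%.

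**Figure D1:**
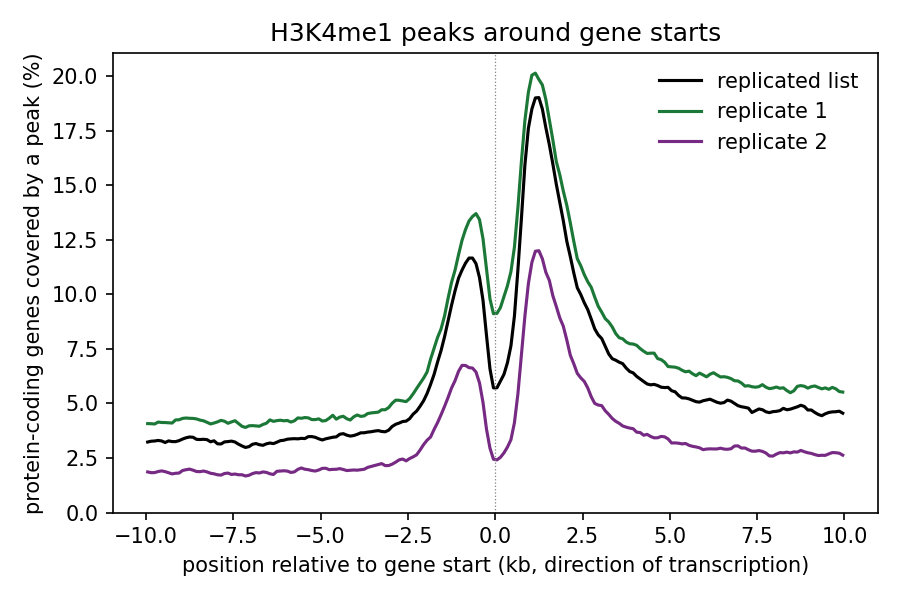
Share of protein-coding genes covered by an H3K4me1 peak (y axis, percent) by position relative to the gene start (x axis, kb, in the direction of transcription), with 1 line each for the replicated list and the lists of replicate 1 and replicate 2. In the replicated list coverage dips to 5.72% at the start between an upstream maximum of 11.7% and a downstream maximum of 19.0%.

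The next comparison asked which cell types' genes carried the mark. The erythroid, stem and progenitor, myeloid and megakaryocyte, and housekeeping lists were covered more than random lists. The hepatoblast list and the lymphoid list (2.62% against 4.84%, log2 ratio -0.89) did not pass the test. Coverage was the percentage of the 100 kb around a gene's 5′ end, 50 kb on each side, that lay in replicated peaks, and its median over all protein-coding genes was 1.83%. The 30 erythroid genes had a mean coverage of 10.2% against 5.21% in random lists matched on gene density, a log2 ratio of 0.96 (replicates 1.01 ± 0.16, SD, n = 2). The 18 genes of blood stem and progenitor cells had 9.76% against 3.28%, a log2 ratio of 1.57 (replicates 1.6 ± 0.10), and the 18 myeloid and megakaryocyte genes 8.81% against 4.35%, a log2 ratio of 1.02 (replicates 0.97 ± 0.05). In contrast, the 30 hepatoblast genes, active in the precursors of hepatocytes, had 3.64% against 4.01%, a log2 ratio of -0.14 whose spread between replicates included 0 (-0.13 ± 0.31).

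In two-sided permutation tests with 10000 random lists, adjusted by the Benjamini-Hochberg method over 12 lists, adjusted p was 0.0008 for the erythroid list and for the stem and progenitor list, which came from the smallest p that the permutations could give (0.0002). Adjusted p was 0.0096 for the myeloid and megakaryocyte list and 0.811 for the hepatoblast list. The difference between the erythroid and hepatoblast lists was itself tested by permuting genes between them, and erythroid coverage was higher by 5.31 percentage points after adjustment for gene density (permutation p = 0.00394, adjusted p = 0.00591 over 3 such differences). Coverage of the stem and progenitor list exceeded that of the hepatoblast list by 6.84 points (permutation p = 0.00187, adjusted p = 0.00561). The 3 pairs of lists compared were not in the plan fixed beforehand, and the adjustment covered only those 3. All these p-values described genes in these peak lists, not animals. The tests of differences between lists counted neighbouring genes with shared windows as independent, which can make p too small. Hbb-y, Hbb-bh1 and Hbb-bs, for example, all had 8.41%, and Fga, Fgb and Fgg all had 0.67%. The differences were not tested again with 1 gene per cluster or without Zfpm1, the most covered erythroid gene. With windows of 10 kb on each side the myeloid and megakaryocyte list no longer passed (log2 ratio 0.50, adjusted permutation p = 0.327, the highest of a range from 0.0060 over its alternatives).

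Among the erythroid genes, 23 of 30 lay above the median gene and 19 above the upper quartile of 6.29%. Zfpm1, which encodes the GATA1 cofactor FOG1, had the most covered window of all protein-coding genes, at 53.4% (replicates 53.2% ± 4.27, SD, n = 2). It was followed in this list by Nfe2, a transcription factor of erythroid cells and megakaryocytes, at 21.4% (18.1% ± 7.26), and by Bcl11a, a repressor of globin genes, at 19.8% (16.9% ± 7.15). Klf1 and Tal1, both erythroid transcription factors, had 13.8% (12.6% ± 4.78) and 13.4% (10.9% ± 5.86). Hbb-y, an embryonic β-type globin gene, had 8.41% (7.30% ± 5.28) in 25 peaks. The erythroid regulator Gata1 had 1.53% (1.10% ± 1.25), and it lies on the X chromosome, where the peak density was 0.0581 of that of the autosomes. Ank1, which encodes ankyrin of the red cell membrane skeleton, had the lowest coverage at 0.210% (0.573% ± 0.810), although a 25.4 kb stretch of 24 peaks, centred in an intron of the gene, lay beyond its window (chromosome 8, mm10, 23036665 to 23062103). Without Zfpm1 the erythroid list had a log2 ratio of 0.71 (permutation test, adjusted p = 0.0256, the highest of a range from 0.0008). The SDs of single genes came from the pair of replicate lists, of which the replicate 1 list covered more of the genome.

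In the stem and progenitor list 13 of 18 genes lay above the median gene. Cbfa2t3, a corepressor in blood progenitors, had 37.3% (36.0% ± 11.2, SD, n = 2), the transcription factor Lyl1 36.2% (32.9% ± 10.03) and Runx1, required for the emergence of blood stem cells, 23.2% (19.0% ± 7.54). Erg, which encodes an ETS transcription factor, was the lowest at 0.252% (0.406% ± 0.574). In the myeloid and megakaryocyte list 11 of 18 genes lay above the median. Elane, the neutrophil elastase gene, had 24.6% (21.3% ± 6.76), Gp9, a platelet glycoprotein gene, 21.7% (18.5% ± 5.40) and Gfi1b, a repressor in erythroid and megakaryocytic cells, 20.6% (17.7% ± 7.07). The window of Ptprc, which encodes the pan-leukocyte protein CD45, held no replicated peak.

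Of the hepatoblast genes, 15 of 30 lay above the median gene and 6 had no replicated peak in their window. Dlk1, a surface protein gene of hepatoblasts, was the most covered at 16.5% (replicates 13.3% ± 7.10, SD, n = 2), ahead of the transcription factor gene Hnf1a at 11.9% (11.97% ± 5.51) and the apolipoprotein gene Apoa2 at 11.1% (10.2% ± 6.09). The strongest peak in the Hnf1a window was 47.8 kb upstream of its start, in an intron of another gene. Blood gene windows also held such peaks, 28.9 kb upstream of Elane and 41.8 and 29.5 kb downstream of the starts of Nfe2 and Lyl1. Those of Zfpm1, Bcl11a and Runx1 lay inside the gene. A replicated peak lay within 2.5 kb of the start in 15 of 30 hepatoblast and 23 of 30 erythroid genes. The same held for 13 of 18 stem and progenitor and 8 of 18 myeloid and megakaryocyte genes. Hnf4a, a transcription factor of the hepatocyte lineage, had 3.31% (3.79% ± 2.43). The windows of Alb and Afp, which encode albumin and alpha-fetoprotein, held no replicated peak, nor did that of Serpina6, which encodes a corticosteroid carrier. Alb had 0.990% coverage and Afp 0.195% in the list of replicate 1, and both had 0 in that of replicate 2.

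The remaining lists covered other cell types that liver tissue could hold, types foreign to it, and general controls. Housekeeping genes had a mean of 9.91% against 5.32%, a log2 ratio of 0.90 (replicates 0.94 ± 0.09, SD, n = 2, permutation test, adjusted p = 0.0096), led by the ribosomal protein gene Rplp0 at 25.5%, the chaperone gene Hsp90ab1 at 23.2% and the translation elongation gene Eef2 at 18.6%. Their coverage differed from that of the erythroid genes by 0.362 points (permutation p = 0.907). Rplp0 had no replicated peak within 2.5 kb of its start, and the strongest peak in its window lay 16.2 kb upstream. X-linked Pgk1 had no replicated peak in its window. The 1134 olfactory receptor genes, a family of sensory neurons, had 0.156% against 5.73%, a log2 ratio of -5.20 (replicates -5.15 ± 0.06, permutation test, adjusted p = 0.0008), and 1034 of them had no replicated peak, Olfr998 among these. The 3 most covered, Olfr66 (10.1%), Olfr64 (9.23%) and Olfr65 (8.78%), are neighbours of the β-globin genes on chromosome 7, and their windows shared their strongest peak with that of Hbb-y.

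Endothelial, lymphoid, neural, adult hepatocyte, mesenchymal and muscle lists did not pass the permutation test. Endothelial genes had a log2 ratio of 0.77 (replicates 0.72 ± 0.11, SD, n = 2, permutation test, adjusted p = 0.0970), with 26.5% at Eng, a co-receptor of vessel cells, 17.2% at Egfl7, 15.1% at Esam and 0 at Emcn. Neural genes had -1.15 (replicates -1.25 ± 0.50, adjusted p = 0.0970 by permutation), with 9.06% at Tubb3, a neuronal tubulin gene, 4.68% at Elavl3, 3.87% at Dlx2 and 0 at X-linked Syn1. Lymphoid genes had -0.89 (replicates -0.86 ± 0.28, adjusted p = 0.117 by permutation), with 9.24% at Cd79a, 9.16% at Lck, 7.99% at Cd4 and 0 at Rag2, which encodes a recombinase subunit. Adult hepatocyte genes had -0.75 (replicates -0.65 ± 0.11, adjusted p = 0.180 by permutation), with 15.0% at Hpd, an enzyme gene of tyrosine breakdown, 12.6% at Cyp1a2, 4.36% at Ass1 and 0 at Ugt2b1. Mesenchymal and stellate genes had -0.34 (replicates -0.48 ± 0.47, adjusted p = 0.797 by permutation), with 11.1% at Pdgfrb, 5.75% at Des, 5.47% at Ngfr and 0 at Lum. Muscle genes had 0.04 (replicates -0.04 ± 0.17, adjusted p = 0.856 by permutation), with 19.2% at Mylk3, 8.88% at Tnni3, 8.79% at Tnnt2 and 0 at Tbx20. Coverage counted every peak in a window, whichever gene it lay in. Among the most covered genes named here, Cd79a, Cd4, Hpd, Cyp1a2, Des and Tnnt2 had no replicated peak within 2.5 kb of their start. The endothelial list passed when peaks were counted in place of covered length, and the neural and adult hepatocyte lists passed under other settings.

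**Figure D2:**
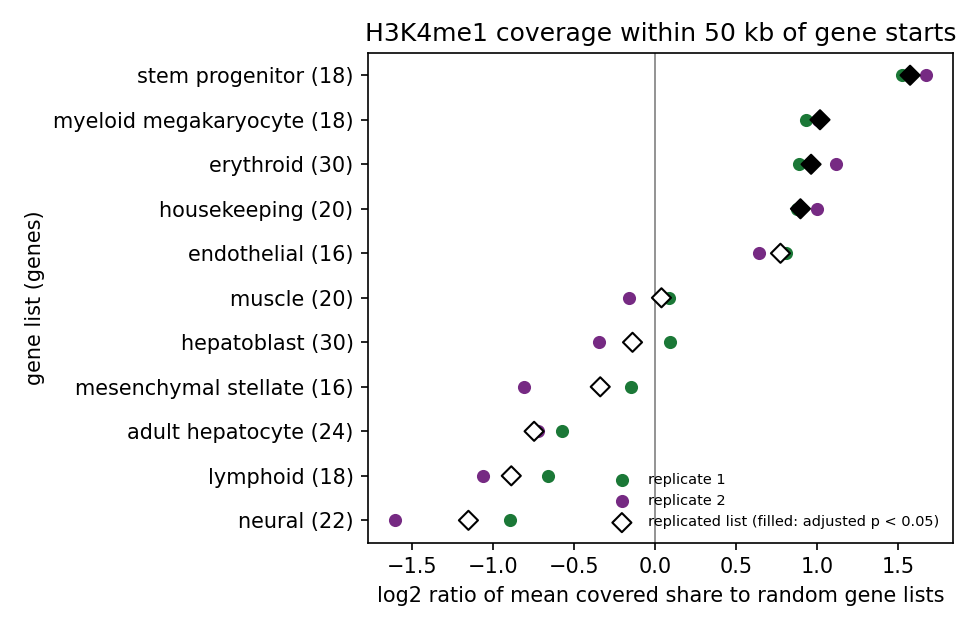
Log2 ratio of mean coverage within 50 kb of gene starts to that of matched random lists (x axis) for 11 gene lists (y axis, number of genes in brackets), with diamonds for the replicated list, filled where adjusted p was below 0.05, and points for each replicate's own list. The erythroid, stem and progenitor, myeloid and megakaryocyte, and housekeeping lists lie between 0.90 and 1.57, the hepatoblast list at -0.14 with its replicates on either side of 0, and the lymphoid list at -0.89.

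The last comparison asked where the longest stretches of the mark lay. Joining replicated peaks separated by at most 1 kb gave 46458 domains with a median length of 599 bp, of which 225 exceeded 10 kb. The longest, 61.5 kb on chromosome 8 (mm10, 120490034 to 120551578), lay in Gse1, and the nearest gene start was that of Gins2, 68.5 kb from its centre. The second, 49.0 kb (chromosome 8, 122284340 to 122333378), lay across the introns and exons of Zfpm1, with 97.6% of its length in replicate 1 peaks and 92.2% in replicate 2 peaks. The third, 40.6 kb (chromosome 14, 25461276 to 25501855), was centred in an intron of Zmiz1, a transcriptional coregulator gene, with 88.3% and 68.4% of its length in peaks of replicate 1 and replicate 2.

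Domains nearest to Stk24 (37.8 kb), Rreb1 (36.5 kb), Actn4 (31.8 kb), Mtss1 (28.6 kb), Gpr146 (28.4 kb), Myh9 (28 kb) and Cxxc5 (26.9 kb) completed the 10 longest, and each overlapped the gene named. Across these 10, replicate 1 peaks covered 67.3% to 97.6% of the domain and replicate 2 peaks 48.1% to 92.2%. Among the 183 genes nearest to the 200 longest domains were 5 of 29 erythroid genes, Ank1, Bcl11a, Lmo2, Sptb and Zfpm1, against 0.391 expected (one-sided Fisher's exact test, p = 3.85e-05, Benjamini-Hochberg adjusted p = 0.000463 over 12 lists). Lmo2, a partner of TAL1 in transcription complexes, and Sptb, the red cell β-spectrin gene, were named because the count was small. The stem and progenitor list had 1 gene there (Cbfa2t3, exact adjusted p = 0.714, but 3 genes and exact adjusted p = 0.00695 with the pooled list, in a range up to 0.955 over its alternatives), the hepatoblast list 1 (Dlk1, exact adjusted p = 0.714) and the housekeeping list 2 (Rplp0 and Ywhaz, exact adjusted p = 0.160). The other 8 lists had 0, at an unadjusted exact p of 1. The erythroid result was lost when only touching peaks were joined (1 gene, exact adjusted p = 0.877) and when peaks were joined across the widest gaps tried (1 gene, exact adjusted p = 1), within a range from 2.09e-05 over all alternatives. The Fisher test was not matched on gene density or gene length. The Lmo2 domain overlapped no gene and was centred 60.2 kb from its start, while those of Ank1, Bcl11a, Sptb and Zfpm1 overlapped the gene named. The Rplp0 domain was centred in an intron of Pxn.

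The strongest replicated peak also lay in Zfpm1. It spanned 28.1 kb of the gene (chromosome 8, 122296083 to 122324166), was centred in an intron 28 kb from the gene start and had a fold enrichment of 11.7. The next were a peak in an intron of Plcb3 nearest to the start of Ppp1r14b (chromosome 19, 6969990 to 6972694, fold enrichment 11.3) and intronic peaks of Dnm2, which encodes the membrane fission protein dynamin 2 (chromosome 9, 21451398 to 21453301, 11.2), Mef2d, a transcription factor gene (chromosome 3, 88143954 to 88151672, 10.6), and Zmiz1 (chromosome 14, 25462631 to 25467103, 10.4). Peaks of replicate 1 covered 93.2% to 99.8% of these 5 peaks and those of replicate 2 covered 71.6% to 97.9%.

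**Figure D3:**
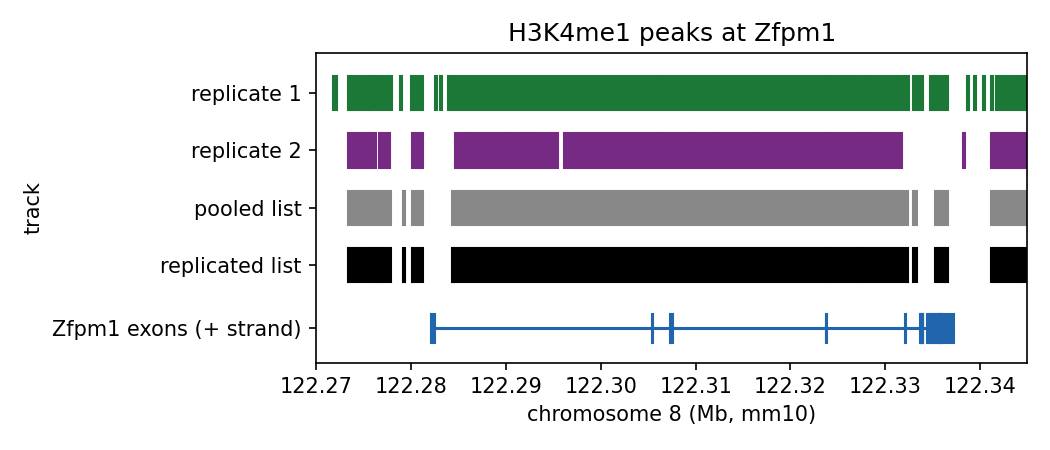
Map of the Zfpm1 gene on chromosome 8 (x axis, position in Mb, mm10) with its exons and, on separate tracks (y axis), the peaks of replicate 1, replicate 2, the pooled list and the replicated list as filled boxes. A 49.0 kb domain of replicated peaks spans most of the gene, with 97.6% of it in replicate 1 peaks and 92.2% in replicate 2 peaks.

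Peaks were unevenly spread over the chromosomes. The 19 autosomes had between 22.2 and 61.1 replicated peaks per Mb, with chromosome 11 the highest, and the X chromosome had 1.94 per Mb (331 peaks). The ratio of the density on X to that on the autosomes together was 0.0581 in the replicated list, 0.0756 in replicate 1 and 0.0330 in replicate 2. Each pool combined male and female embryos, according to the labels.

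**Figure D4:**
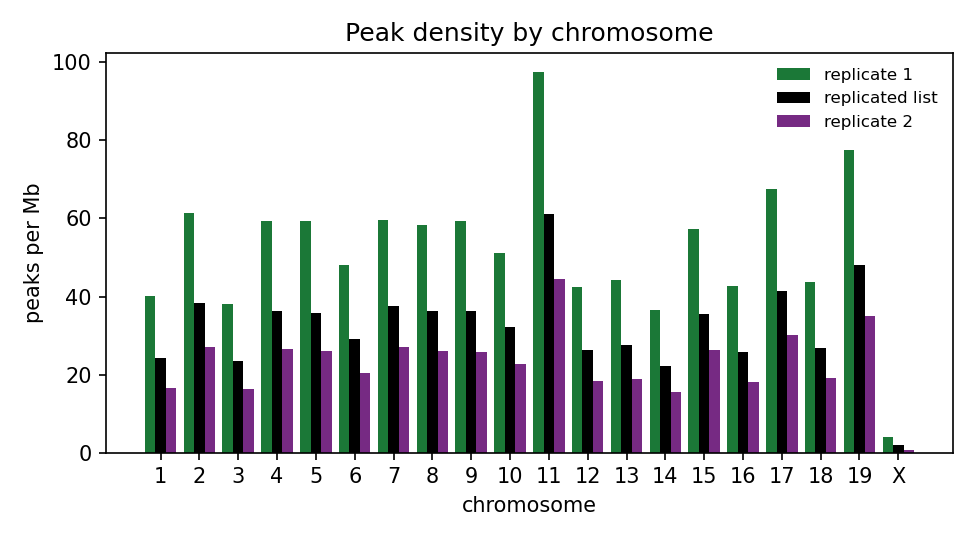
Peaks per Mb (y axis) on each chromosome (x axis) in the lists of replicate 1 and replicate 2 and in the replicated list, shown as bars. The X chromosome, at 1.94 per Mb in the replicated list, lies below every autosome, the lowest of which has 22.2.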

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

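Of 343 values recomputed under alternative settings, 294 kept their direction and their side of the threshold or moved by less than their spread, and 49 changed. The 294 overstate stability, because some of them could hardly change. The overlap rule does not enter the share of pooled peaks kept. Several lists had no gene near the longest domains under any setting. Lists without clustered genes were unaltered by taking 1 gene per cluster. Changes in the number of passing lists also counted as kept. The settings without the most covered gene, with peaks in both replicates, with autosomal genes only and with top peaks were chosen after the data were seen. The erythroid list (log2 ratio 0.71 to 1.25), the stem and progenitor list (1.19 to 1.72), housekeeping genes (0.72 to 1.21) and olfactory receptors (-7.09 to -4.13) passed under all 13 alternatives, and 5 to 7 lists passed in each. Unknown depth limits every share, and where a result changed the cause was not tested.

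The share of replicate 2 peaks found in replicate 1 was 83.1% with an overlap of 1 bp, 40.7% with 50% of both peaks, 77.5% at a q-value of at most 0.01, 56.1% with equal list lengths and 78.4% with merged peaks. For replicate 1 peaks the same settings gave 34.9%, 17.8%, 23.4%, 48.9% and 34.4%. The share of replicated peaks in both replicates was 50.6% with 1 bp, 29.2% with 50% of both, 37.9% at the stricter q-value and 35.7% with top peaks, and the share of pooled peaks kept was 90.4% at the stricter q-value. The promoter share was 40.4% within 2.5 kb, 24.5% with merged peaks and 21.2% to 22.7% when either replicate was left out.

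Without either replicate the hepatoblast log2 ratio was -0.34 to 0.0936, the neural -1.61 to -0.89 and the muscle -0.16 to 0.0832. The neural list passed in the list of replicate 2 alone (permutation test, adjusted p = 0.0400, range over its alternatives 0.0072 to 0.416). Counting peaks gave 0.0383 for hepatoblast genes and 0.85 for endothelial genes, which then passed (adjusted permutation p = 0.0184, range to 0.363). Windows of 10 kb gave 0.50 for the myeloid and megakaryocyte list, which no longer passed, -2.06 for adult hepatocyte genes, which then passed, and -0.21 for muscle. Windows of 100 kb gave 0.17 for mesenchymal and -0.15 for muscle genes. Without density matching the adult hepatocyte (-1.10) and neural (-1.59) lists passed, as they did without their most covered gene (-1.23 and -1.54), and muscle genes had -0.32 and -0.37. Leaving out the most covered gene lowers a list's mean by construction, while the random lists keep theirs. Passing as a low list under that setting is therefore no evidence of low coverage. With peaks in both replicates neural genes passed at -1.63 and muscle genes had -0.0633. Muscle genes had -0.10 at the stricter q-value and -0.0299 among autosomal genes, and passed under no setting.

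For the longest domains, 1 erythroid gene was left when only touching peaks were joined (gap of 0) and 1 with the widest gap, and 0 lists passed in both. With the pooled list 2 lists passed, the erythroid list and the stem and progenitor list, which had 3 genes (Fisher's exact test, adjusted p = 0.00695). No paired analysis was possible because there was only 1 group.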

Other observations

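The loci named in this paragraph were chosen after their values were seen. Outside the fixed lists, the most covered windows, counting 1 gene per 100 kb, were those of Hipk2, a nuclear kinase gene, at 48.9% (replicates 42.5% ± 11.4, SD, n = 2), Zmiz1 at 44.7% (40.8% ± 7.86), Nol4l at 44.4% (40.9% ± 10.8), 4930404N11Rik at 43.7% (37.3% ± 14.9) and Rara, the retinoic acid receptor alpha gene, at 42.8% (37.0% ± 11.4). They were followed by Smad6 at 42.04% (36.9% ± 12.47) and Smad3 at 40.3% (35.7% ± 9.07), an inhibitory and a receptor-activated member of the SMAD family that carries signals of the TGF-β superfamily. The 25 peaks in the Hbb-y window included its strongest at chromosome 7, 103869432 to 103869741 (mm10, intergenic, fold enrichment 5.38), 16.4 kb upstream of Hbb-y, the side on which the locus control region of the β-globin genes lies.

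The tests chosen only after the result was seen were those of blood cells, of list length and of weak peaks in the 3 paragraphs that follow. The tests of differences between lists were not in the plan fixed beforehand either. No biological explanation was tested by a comparison of groups, since the design had 1.

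The X chromosome held few peaks. Gene density is argued against as the whole cause, because X genes had 0.0542 of the coverage of autosomal genes with as many gene starts in the window, while the lowest autosome had 0.608. Repeat-rich sequence between genes is also argued against, because 6.65% of X genes had a replicated peak within 2.5 kb of their start, against 40.1% to 65.7% on the autosomes. A lower signal close to the detection threshold may contribute, since the median fold enrichment of X peaks (3.33) lay below that of every autosome (3.56 to 3.65) and the density ratio to autosomes was lower in the shorter list of replicate 2 (0.0330) than in that of replicate 1 (0.0756). What would lower the signal on X, such as a single active copy per cell or any control used in peak calling, stays open and untested.

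Hepatoblast genes had less coverage than erythroid genes, and Alb and Afp had no replicated peak within 50 kb. A detection threshold that hides weaker hepatoblast peaks was examined in the longer list of replicate 1. There the erythroid genes still had more coverage (permutation p = 0.0149, adjusted p = 0.0223 over 3 differences). That list too held only peaks with a −log10 p above 2, so it cannot exclude such a threshold. The hepatoblast log2 ratio was 0.0936 in that list and -0.34 in the shorter list of replicate 2. A window too narrow for sites within 100 kb is argued against as the whole cause, because erythroid coverage stayed higher with 100 kb on each side (permutation p = 0.0197, adjusted p = 0.0295). The difference was 3.81 points there against 5.31 with 50 kb, so a contribution of more distant sites stays open. A candidate explanation is that blood cells made up most of the tissue, as the stem and progenitor list (log2 ratio 1.57) and the myeloid and megakaryocyte list (1.02, but 0.50 and not past the threshold with windows of 10 kb) also lay above random lists. The housekeeping list was raised alike (0.90), the lymphoid list (-0.89, not past the threshold) decides nothing either way, and without a tissue free of blood cells this explanation cannot be told apart from other causes.

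Replicate 1 had more peaks than replicate 2 and shared a smaller percentage of them. With replicate 1 kept to as many top peaks as replicate 2 had, the shares found in the other list came to 48.9% and 56.1%, against 29.9% and 74.3% with the full lists. Unequal list length may therefore account for most of that gap, but lists of equal length bring the shares close together by construction, so how much length alone explains stays open. Weak peaks close to the detection threshold may also contribute, since 82.5% of the top decile of replicate 1 peaks by p-value were shared against 11.4% of the bottom decile. Shared peaks were also wider, and this was not separated from strength. Depth, pool size and any control used for each replicate could not be compared with the files at hand.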
